A study of Rattus norvegicus with 18 samples.

How the data were processed

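RNA sequencing of phenylephrine-treated neonatal rat ventricular cardiomyocytes was analysed in 18 libraries: 3 each of cells infected with adenovirus carrying sORF6, sORF7 or sORF8 and 3 each of the control virus of every sORF. Total RNA was extracted with Trizol and libraries were sequenced on a BGIseq instrument, per the labels. Group and replicate number were taken from the sample titles. All 18 libraries entered the analysis, and every per-sample column of the table matched a sample.

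The authors deposited 1 table of 19880 genes, all of type mRNA, with 4 kinds of value. The estimated counts per gene and library are, per the submitters' processing notes, the work of tools that include HISAT2 2.0.4 and RSEM 1.2.12 on genome build Rnor_6.0. The notes name the tools without roles, and whether counting used strand is not given in the sources used here. The FPKM values the authors deposited are relative to the column totals of the same table, within 0.119%. The authors' log2 fold changes equal the log2 ratio of summed group counts plus a constant. The authors' q-values stand in columns headed degseq, per the file headers, while the submitters' processing notes name DESeq2 1.4.5. These deposited q-values are used only where the authors' deposited table is named. Genes of the mitochondrial chromosome, non-coding RNAs and viral transcripts were not analysed here. Because RSEM divides reads among similar transcripts, genes with near-identical copies are reported as uncertain. Effective transcript length was derived as the count divided by the FPKM and the column total. Positions are those of the deposited table, and no genome sequence was used here. Symbols are those of the table, where 5 symbols are carried by 2 genes each.

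The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were filtered by filterByExpr with the 6 groups, which kept 14872. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, leaving 12 residual degrees of freedom and a common biological coefficient of variation of 6.90%. Each sORF was compared with its own control virus, differences between experiments were tested as differences of these differences, and the 3 control groups were compared by a joint F test. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over the genes tested, and were called at an adjusted p under 0.05. Normalised CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries. The ± after a log2 fold change is its standard error.

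Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Of 31 lists, 30 were tested: hypertrophy and fetal cardiac genes, sarcomere, calcium handling, ion channels and junctions, oxidative phosphorylation, fatty acid oxidation, glycolysis, hypoxia, immediate early, MAPK feedback, TGF-beta and YAP, markers of fibroblasts, smooth muscle, endothelium, leukocytes, epicardium, Schwann cells and erythroid cells, interferon-stimulated genes, NF-kB and cytokines, endoplasmic reticulum chaperones, integrated stress response, heat shock, mitotic, DNA replication, p53, NRF2, cholesterol synthesis, autophagy and lysosome, and ribosomal proteins. The list of 26 names for mitochondrially encoded genes had 0 measured members and was not tested. Lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists of a comparison. The named genes were, per experiment, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups, leaving out unnamed loci. To these were added Nppa, Nppb, Myh7, Myh6, Acta1 and Atp2a2, the 3 members with the smallest adjusted p of each called list, and the 3 genes with the smallest p for each difference between experiments. Genes outside the rule are named as such, and some genes that meet it are not reported here.

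Depth was 15697177 to 17658137 counts per library. The edgeR test was run on simulated counts for the 14872 genes with known changes in 50 genes per fold. At 1.25-fold it recovered 24% of changed genes for sORF6, 26% for sORF7 and 40% for sORF8. At 1.5-fold these shares were 54%, 68% and 68%, at 2-fold 82%, 76% and 74%, and at 4-fold 96%, 92% and 100%. Of 14652 unchanged genes, 7, 3 and 8 were called. Camera gave a p under 0.05 for 0 of 100 unchanged lists in each case. The simulated genes were drawn independently of each other, so these lists do not test the preset correlation where members vary together. The tests of differences between experiments, the joint F test, the DESeq2, limma, blocked and length-corrected fits were tested on the same simulated counts. Of the 100 genes changed at least 2-fold they recovered 74% or more. Changes under 2-fold were therefore often missed in these simulated counts.

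Within groups, no pair of libraries held identical values, and chi-square per degree of freedom over genes was 2.75 to 11.4, above sampling noise for each of the 18 pairs. Control replicate 2 of the sORF6 experiment gave the 2 highest values (11.2 and 11.4). Alternatives planned before the data were examined were RLE size factors, no low-count filter, DESeq2 1.42.0, limma on log2(FPKM + 1), a fit of each experiment alone, a block for replicate number, a 2-fold threshold, an estimated list correlation and leaving out each library. Alternatives chosen after seeing the data were leaving out 2 control libraries that stood apart, thinning all libraries to the lowest total, an offset that removes each library's trend with effective transcript length, and leaving out each control library in the joint test. Pathway annotation of the table was tested with camera after the data were seen. Tables were handled with Python 3.11.15.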

Results

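RNA was sequenced from neonatal rat ventricular cardiomyocytes, primary muscle cells isolated from the ventricles of Sprague-Dawley rats on postnatal day 2. Every culture had received phenylephrine, an agonist of alpha-1 adrenergic receptors that induces hypertrophic growth of cardiomyocytes, at 20 µM for 24 h. The cells were infected with an adenovirus carrying 1 of 3 short open reading frames (sORFs), called sORF6, sORF7 and sORF8, or with a control virus. Each sORF had its own control group, so the 18 libraries formed 6 groups of 3. The labels do not give the sequence or the peptide of any sORF, and they do not say whether the 3 libraries of a group came from separate cultures. The p-values below therefore measure only the spread between these libraries, which may be technical. Total counts per library ran from 15697177 to 17658137, with the lowest totals in the control group of sORF8. Actc1, the cardiac alpha actin gene, was the most abundant gene in each of the 18 libraries. Of 19880 genes in the table, 14872 passed the filter on low counts and were tested.

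The first 2 principal components held 32.1% and 21.9% of the variance over 12511 expressed genes. The 6 libraries of the sORF8 experiment lay apart from the other 12 on the first component. On the second, the sORF6 libraries lay at the top and the sORF7 libraries at the bottom, with the controls of both in between.

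**Figure D1:**
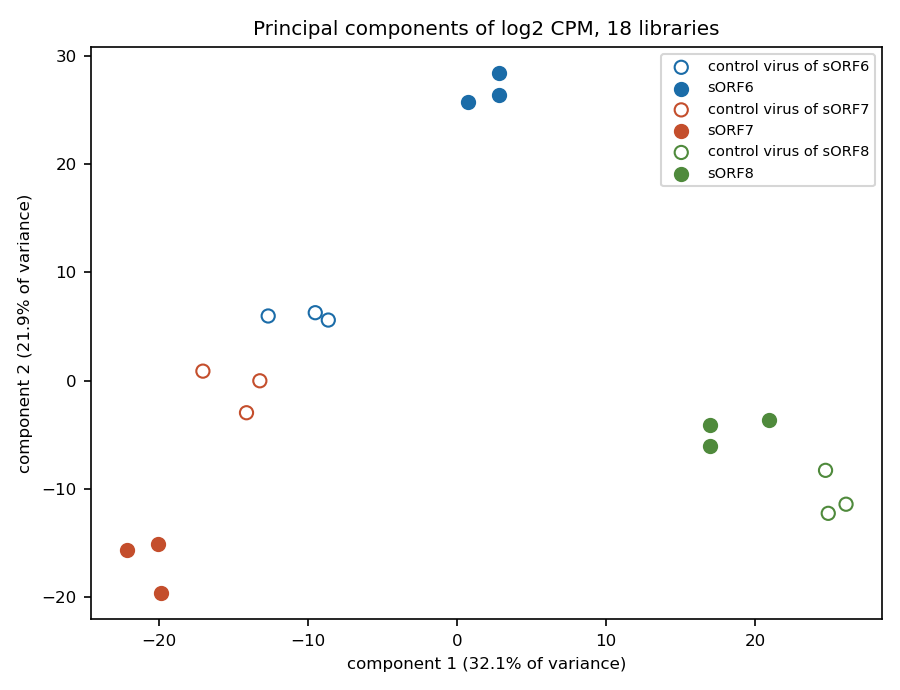
Principal components of log2 CPM (counts scaled to library size) of 18 libraries, with component 1 (32.1% of the variance) on the horizontal axis and component 2 (21.9%) on the vertical axis, both in component units. Each point is a library, filled for an sORF virus and open for its control virus, and the 6 libraries of the sORF8 experiment lie to the right of the other 12.

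The first comparison asked which genes the sORF6 virus changed in phenylephrine-treated cardiomyocytes, relative to its own control virus. Interferon-stimulated genes, the antiviral programme that cells start after sensing viral nucleic acid or interferon, were lower with sORF6. Of 44 members tested, 38 fell and 0 rose (39 and 0 adjusted over the list alone), and the list median was 3.67-fold lower. Genes of NF-kB signalling and inflammatory cytokines fell as well, in 20 of 27 members. In the other direction, Nppa, which encodes atrial natriuretic peptide and marks hypertrophic and fetal cardiac expression, rose from 4265 ± 394 to 5405 ± 98.6 normalised CPM (SD, n = 3 each). In all, 574 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 145 higher and 429 lower, while limma on log2(FPKM + 1) called 92 higher and 434 lower.

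Usp18, a protease that removes ISG15 from proteins and restrains interferon signalling (gene 312688, chromosome 4, 153805834 to 153834374, plus strand, Rnor_6.0), fell from 55.0 ± 11.9 to 5.42 ± 0.832 normalised CPM (SD, n = 3 each). Its log2 fold change was -3.34 ± 0.22 (SE), with an edgeR adjusted p of 2.97e-08. Irf7, the transcription factor that amplifies the interferon response (gene 293624, chromosome 1, 214249388 to 214252909, minus strand), fell from 75.1 ± 15.1 to 8.23 ± 1.15 normalised CPM. Within the limits on level and overlap of the naming rule, the other largest falls were those of Rtp4 (log2 fold change -3.30), Oas1a (-3.25), Isg15 (-3.07), Rsad2 (-2.96) and Mx2 (-2.94), all interferon-stimulated, and of Nos2 (-3.24), the inducible nitric oxide synthase. Oas1b, with a log2 fold change of -2.39 ± 0.15, had the smallest adjusted p of the interferon list. Oas1a, Oas1b and Mx2 have close paralogs that could share reads, so their values are uncertain. The interferon list median was a log2 fold change of -1.87, and the list was called with an edgeR-based camera adjusted p of 3.49e-206 at the preset correlation and 8.41e-05 with an estimated correlation. The erythroid markers had a median of -2.03 over 5 genes near the detection limit. None of the 5 passed the test over all genes (3 fell adjusted over the list alone), and the list was called with a camera adjusted p of 0.0142 (adjusted p = 0.228 with an estimated correlation, and 0.0725 at the preset one without control replicate 1). Its members with the smallest p were Hba2 (log2 fold change -2.03 ± 0.68), Hba-a1 (-3.46 ± 1.14) and Hbb (-2.44 ± 0.90), globin genes with close copies.

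**Figure D2:**
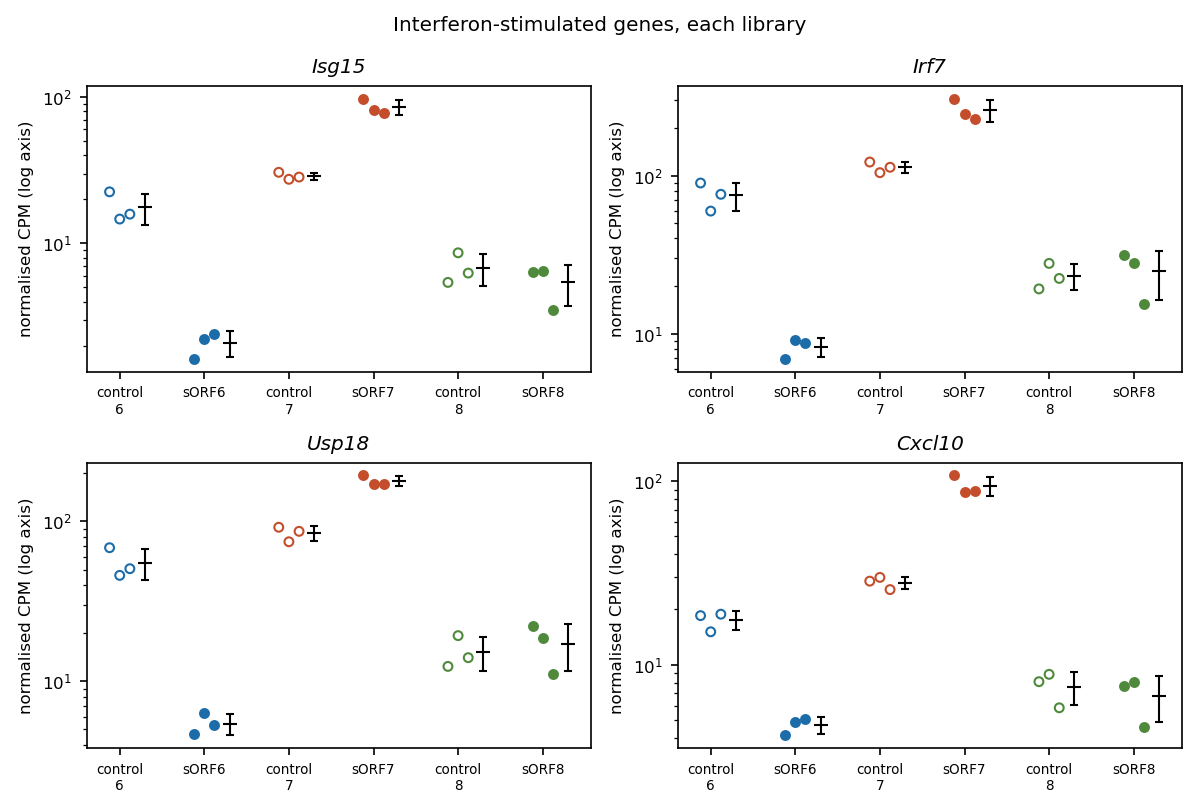
Normalised CPM (log axis) of Isg15, Irf7, Usp18 and Cxcl10 in each library, by group, with 3 points per group, filled for an sORF virus and open for its control virus, and the mean ± SD beside them. Usp18 averaged 5.42 with sORF6 against 55.0 in its control, 179 with sORF7 against 84.3, and 17.2 with sORF8 against 15.2.

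Among the NF-kB and cytokine genes, the list median was -0.67 and 24 of 27 members fell adjusted over the list alone (camera adjusted p = 2.54e-73, and 1.53e-06 with an estimated correlation). Ccl2, a monocyte chemokine, had a log2 fold change of -1.75 ± 0.11 and fell in all 3 libraries below each of the 3 controls. Cxcl1, a neutrophil chemokine, had a log2 fold change of -1.95 ± 0.13, and Lcn2, a secreted iron-binding acute phase protein, one of -1.39 ± 0.09. Macrophage and leukocyte markers were not called as a list (median -0.28, camera adjusted p = 0.167), with 2 of 15 members lower and 0 higher (6 and 2 adjusted over the list alone). The p53 targets had a median of -0.10 (camera adjusted p = 0.00362, and 0.0310 with an estimated correlation), where 2 of 20 members fell (6 adjusted over the list alone). These were Cdkn1a, the p21 inhibitor of cyclin-dependent kinases (log2 fold change -0.30 ± 0.03), and Ccng1, cyclin G1 (-0.15 ± 0.04), while Aen had a value of -0.17 ± 0.05 with an edgeR adjusted p of 0.0692. Of 27 DNA replication genes, 6 fell (12 adjusted over the list alone), among them the replicative helicase subunits Mcm6 (-0.35 ± 0.04), Mcm3 (-0.32 ± 0.05) and Mcm5 (-0.28 ± 0.06). That list had a median of -0.15 and a camera adjusted p of 2.84e-07 (adjusted p = 0.131 with an estimated correlation).

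Some cardiac genes rose with sORF6. Of 16 hypertrophy and fetal cardiac genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone): Nppa (log2 fold change 0.34 ± 0.05), Myl4 (0.27 ± 0.06), Myh7 (0.25 ± 0.06), Nppb (0.23 ± 0.06) and Fhl1 (0.13 ± 0.03). The list median was 0.11, with a camera adjusted p of 1.91e-05 (adjusted p = 0.131 with an estimated correlation). Of 29 sarcomere genes, 6 rose, among them Myom2 (0.35 ± 0.06), Synpo2l (0.18 ± 0.04) and Pdlim5 (0.12 ± 0.03), and Myh6, the adult alpha myosin heavy chain, fell (-0.32 ± 0.07), giving a median of 0.08 and a camera adjusted p of 1.36e-05 (adjusted p = 0.190 with an estimated correlation). Adjusted over the list alone, 9 sarcomere genes rose and 1 fell. Myh6 and Myh7 are close paralogs whose intervals overlap on chromosome 15 in the table, so reads can be split between them. Acta1 (0.11 ± 0.05) and Atp2a2 (0.00 ± 0.04) did not pass, with edgeR adjusted p of 0.346 and 0.991. Glycolysis genes had a median of -0.04 and a camera adjusted p of 0.0288 (adjusted p = 0.487 with an estimated correlation, and 0.352 at the preset one without control replicate 2). Its 1 member that fell, also adjusted over the list alone, was Slc2a4, the insulin-responsive glucose transporter (-0.55 ± 0.08), while Pgk1 (-0.11 ± 0.04) and Pfkp (-0.09 ± 0.03) did not pass.

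Among called, named loci with a mean log2 CPM of at least 1 and no overlap between groups, the 8 with the largest rises were Cyp1a1 (log2 fold change 1.30 ± 0.29), a target of the aryl hydrocarbon receptor, the scavenger receptor gene Stab1 (1.24 ± 0.14), Capns1 (0.77 ± 0.21), Fam180a (0.68 ± 0.10), Dlk1 (0.65 ± 0.10), Selenop (0.59 ± 0.07) and the collagen genes Col6a6 (0.58 ± 0.15) and Col8a2 (0.56 ± 0.05). Stab1 (gene 100363145, chromosome 16, 7220434 to 7250934, minus strand) rose from 4.81 ± 0.135 to 11.4 ± 0.584 normalised CPM. Capns1 has near-identical copies and is uncertain. Of the 574 genes, 136 changed at least 2-fold, 4 upward and 132 downward. The 4 were Cyp1a1, Stab1, LOC102547056 and LOC108349573, and the last pair was named after the values were seen.

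The remaining lists were not called with sORF6. Markers of other cell types had medians of 0.06 for cardiac fibroblasts (camera adjusted p = 0.0702), 0.07 for smooth muscle and pericytes, 0.08 for endothelium, 0.10 for epicardium and 0.20 for Schwann and neural crest cells. Medians were 0.06 for calcium handling (camera adjusted p = 0.0749), 0.00 for cardiac ion channels and junctions, -0.05 for nuclear-encoded oxidative phosphorylation (camera adjusted p = 0.0610) and 0.01 for fatty acid oxidation. Cholesterol synthesis (0.06, camera adjusted p = 0.0544) and the NRF2 and antioxidant genes (-0.04, camera adjusted p = 0.0604) lay closest to the threshold. Hypoxia targets (0.01), immediate early genes (-0.04), MAPK feedback genes (0.00), TGF-beta and YAP targets (0.02), endoplasmic reticulum chaperones (0.01), the integrated stress response (-0.03), heat shock genes (-0.05), mitotic genes (0.04), autophagy and lysosome (-0.04) and cytosolic ribosomal proteins (-0.03) completed the set. For endothelial markers and hypoxia targets the mean was negative (-0.03 for both) where the median was positive, and for hypoxia targets the test direction was down. With 1 library left out, oxidative phosphorylation passed as lower without control replicate 3 (camera adjusted p = 6.32e-06), control replicate 1 (0.00101) or sORF6 replicate 2 (0.0010). It did not pass with an estimated correlation (camera adjusted p = 0.732) or with the length correction chosen after seeing the data (0.866). The NRF2 list passed in 4 such fits (lowest 0.032, without control replicate 3), and calcium handling (0.0313, without sORF6 replicate 3), fibroblast markers (0.0285, without control replicate 1) and cholesterol synthesis (0.0197, without sORF6 replicate 1) in 2 each.

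Between the 3 sORF6 and the 3 control libraries, 3061 genes (20.6%) had no overlap, where chance gives 10%. Fewer genes passed without sORF6 replicate 1 (368) or replicate 3 (372), and 318 passed in a fit of only these 6 libraries. Named genes that lost their call in some fits with 1 library left out, each with its largest edgeR adjusted p among them and the log2 fold change there, were Nppb (0.182 at 0.19 without control replicate 1), Myh7 (0.128 at 0.22 without sORF6 replicate 1), Myh6 (0.0821 at -0.23 without control replicate 1), Capns1 (0.181 at 0.61 without control replicate 2), Col6a6 (0.158 at 0.50 without sORF6 replicate 1), Cyp1a1 (0.0822 at 1.16 without sORF6 replicate 1), Myl4 (0.0786 at 0.23 without sORF6 replicate 3), Fhl1 (0.0787 at 0.12 without control replicate 1), Pdlim5 (0.0546 at 0.11 without control replicate 1) and Ccng1 (0.106 at -0.15 without sORF6 replicate 1). Capns1 lost its call whichever of the 6 libraries was left out, and Nppb lost it in 5 of the 6 fits. In the fit of only the 6 libraries, the calls of Myl4 (edgeR adjusted p = 0.0979), Myh7 (0.181), Nppb (0.186), Fhl1 (0.161), Myh6 (0.115), Pdlim5 (0.139), Ccng1 (0.0897) and Col6a6 (0.0545) ended. Control replicate 2 stood apart from the other control libraries, and leaving it out together with control replicate 1 of the sORF7 experiment, a choice made after seeing the data, gave 623 genes. Across 12511 genes, the fold changes had a Spearman rho with effective transcript length of 0.228 for sORF6, -0.129 for sORF7 and 0.0556 for sORF8.

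The second comparison asked the same of sORF7. Interferon-stimulated genes, lower with sORF6, were higher with sORF7: 40 of 44 members rose and 0 fell (41 and 0 adjusted over the list alone), with a list median 1.88-fold higher. Cholesterol synthesis genes fell in 17 of 22 members. Hypertrophy genes fell too, among them Nppa, from 3859 ± 286 to 3054 ± 136 normalised CPM (SD, n = 3 each), and Myh7, the fetal beta myosin heavy chain of rodent ventricle, from 12070 ± 720 to 8759 ± 306. Antioxidant genes under the transcription factor NRF2 rose in 10 of 24 members. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1156 genes passed, 612 higher and 544 lower.

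Cxcl10, an interferon-induced chemokine (gene 245920, chromosome 14, 17210733 to 17212930, plus strand, Rnor_6.0), rose from 28.0 ± 2.16 to 94.4 ± 11.2 normalised CPM (SD, n = 3 each). Its log2 fold change was 1.75 ± 0.13, with an edgeR adjusted p of 3.56e-07. Oasl (gene 304545, chromosome 12, 47444138 to 47456680, minus strand) rose from 24.4 ± 0.988 to 81.2 ± 5.20. Within the same limits, the other largest rises were those of Rtp3 (log2 fold change 2.37 ± 0.39), Rsad2 (1.63 ± 0.20), the receptor tyrosine kinase gene Ret (1.60 ± 0.32), Bst2, which tethers budding virions (1.58 ± 0.15), Isg15 (1.57 ± 0.15) and Tnf (1.46 ± 0.21). The interferon list had a median of 0.91 and a camera adjusted p of 1.83e-70, and 0.00543 with an estimated correlation. Of 27 NF-kB and cytokine genes, 15 rose (18 adjusted over the list alone), among them Ccl2 (0.66 ± 0.10) and Cx3cl1 (0.33 ± 0.05), and 1 fell by either count. That 1 was Vcam1 (-0.21 ± 0.06), named after its value was seen. The list median was 0.33, with a camera adjusted p of 7.07e-17, and 0.00123 with an estimated correlation.

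Cholesterol synthesis genes had a median of -0.22 with sORF7 (19 of 22 fell adjusted over the list alone), with a camera adjusted p of 1.05e-27, and 0.000209 with an estimated correlation. Hmgcs1, HMG-CoA synthase (gene 29637, chromosome 2, 52427351 to 52445082, plus strand), fell from 629 ± 29.9 to 505 ± 7.74 normalised CPM. Sqle, squalene epoxidase, had a log2 fold change of -0.29 ± 0.03, and Hsd17b7 one of -0.55 ± 0.06. Of the NRF2 and antioxidant genes, 10 rose by either count, with a median of 0.15 and a camera adjusted p of 3.49e-15, and 0.00105 with an estimated correlation. The members with the smallest p were Hmox1, heme oxygenase (0.58 ± 0.06), the autophagy receptor gene Sqstm1 (0.48 ± 0.05) and Srxn1, sulfiredoxin (0.61 ± 0.07). Autophagy and lysosome genes rose in 8 of 26 members (10 adjusted over the list alone), among them Ctsd (0.26 ± 0.04) and Lamp1 (0.22 ± 0.03), with a median of 0.11 and a camera adjusted p of 2.74e-08, and 0.0377 with an estimated correlation. Sqstm1 is also a member of that list. The p53 targets had a median of 0.16 (camera adjusted p = 0.00220, and 0.0148 with an estimated correlation), with 4 of 20 higher and 1 lower (5 and 2 adjusted over the list alone). Cdkn1a (0.22 ± 0.03), Mdm2 (0.32 ± 0.05), Aen (0.26 ± 0.05) and Bax (0.23 ± 0.06) rose and Perp fell (-0.15 ± 0.04), the last pair named after the values were seen.

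Contractile and hypertrophy genes were lower with sORF7. Of 16 hypertrophy and fetal cardiac genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.21 and a camera adjusted p of 2.13e-12, and 0.00740 with an estimated correlation. Log2 fold changes were -0.46 ± 0.06 for Myh7, -0.34 ± 0.05 for Nppa, -0.31 ± 0.03 for the cardiac transcription factor gene Gata4, -0.31 ± 0.04 for Ankrd1, -0.28 ± 0.06 for Nppb and -0.28 ± 0.05 for Acta1. The 1 that rose was Gdf15 (0.35 ± 0.08), a stress-induced cytokine named after its value was seen. Myh6 (0.20 ± 0.07) and Atp2a2 (-0.09 ± 0.04) did not pass, with edgeR adjusted p of 0.0971 and 0.181. Myh6 passed as higher in the fit of only the 6 libraries (edgeR adjusted p = 0.0471) and with the length correction chosen after seeing the data (0.0221). Of 29 sarcomere genes, 11 fell and 0 rose (19 and 1 adjusted over the list alone), among them Myom1 (-0.31 ± 0.04), Actn2 (-0.22 ± 0.03) and Pdlim5 (-0.20 ± 0.03), with a median of -0.16 and a camera adjusted p of 8.21e-16, and 0.00817 with an estimated correlation. TGF-beta and YAP targets fell in 7 of 21 members and rose in 1 (10 and 3 adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 0.00368, and 0.0395 with an estimated correlation. In that list Ankrd1 and Ctgf (-0.13 ± 0.03) fell.

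Cardiac fibroblast markers moved with these genes: 5 of 20 fell (8 adjusted over the list alone), among them Col6a1 (-0.23 ± 0.04), Col3a1 (-0.21 ± 0.04) and Postn (-0.16 ± 0.04), with a median of -0.11 and a camera adjusted p of 0.00158 (adjusted p = 0.185 with an estimated correlation). Calcium handling genes had a median of -0.07 and a camera adjusted p of 0.00376 (adjusted p = 0.149 with an estimated correlation), where Casq2 (-0.16 ± 0.03) and Cacna1g (-0.25 ± 0.05) fell with 3 others, and Adrb1, the beta-1 adrenergic receptor, rose (0.35 ± 0.07). Adjusted over the list alone, 6 fell and 1 rose. Glycolysis genes rose in 4 of 21 members (6 adjusted over the list alone), among them Slc2a4 (0.47 ± 0.07), Pkm (0.16 ± 0.03) and Pgam1 (0.11 ± 0.03), with a median of 0.05 and a camera adjusted p of 0.00218 (adjusted p = 0.285 with an estimated correlation). Hypoxia targets rose in 4 of 19 (5 adjusted over the list alone), among them P4ha2 (0.22 ± 0.04), Vegfa (0.15 ± 0.04) and Adm (0.43 ± 0.10), with a median of 0.06 and a camera adjusted p of 0.00903 (adjusted p = 0.0562 with an estimated correlation). Integrated stress response targets rose in 9 of 25 and fell in 2 (10 and 3 adjusted over the list alone), with Trib3 (0.44 ± 0.07), Ddit3 (0.40 ± 0.07) and Ppp1r15a (0.30 ± 0.05) higher, a median of 0.08 and a camera adjusted p of 7.08e-05 (adjusted p = 0.101 with an estimated correlation). The 2 that fell were Asns (-0.23 ± 0.04) and Mthfd2 (-0.19 ± 0.04), enzymes of amino acid and folate metabolism named after their values were seen.

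Mitotic genes had a median of -0.16 with sORF7 and a camera adjusted p of 6.73e-06 (adjusted p = 0.149 with an estimated correlation), where Ccnb1 (-0.56 ± 0.10) and Ndc80 (-0.37 ± 0.09) fell, 8 of 30 fell adjusted over the list alone, and Nusap1 (-0.27 ± 0.08) had an edgeR adjusted p of 0.0509. Cytosolic ribosomal proteins had a median of 0.04 and a camera adjusted p of 0.0146 (adjusted p = 0.820 with an estimated correlation, and 0.942 at the preset one without control replicate 1). Its 3 of 74 members that rose (2 adjusted over the list alone) were Rpl38 (0.87 ± 0.11), Rpl9 (0.46 ± 0.10) and Rpl28 (0.22 ± 0.06), genes with many processed copies. Within the limits on level and overlap, the 8 largest falls were those of Acot1 (-1.48 ± 0.25), Olfml2a (-1.05 ± 0.23), Ermap (-1.01 ± 0.23), Fcrl2 (-0.91 ± 0.22), Dpp4 (-0.88 ± 0.16), Lingo4 (-0.87 ± 0.25), Tsen34l1 (-0.83 ± 0.23) and Ceacam1 (-0.78 ± 0.23). Acot1, an acyl-CoA thioesterase, fell from 2.59 ± 0.315 to 0.922 ± 0.0353 normalised CPM. Acot1 and Tsen34l1 have close copies and are uncertain.

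The other lists were not called with sORF7. Medians were 0.03 for cardiac ion channels and junctions (camera adjusted p = 0.0744), 0.02 for nuclear-encoded oxidative phosphorylation, 0.01 for fatty acid oxidation, 0.01 for immediate early genes, 0.02 for MAPK feedback genes, 0.02 for endoplasmic reticulum chaperones, 0.00 for heat shock genes and 0.03 for DNA replication genes. For other cell types they were 0.00 for smooth muscle and pericytes, -0.05 for endothelium, -0.05 for macrophages and leukocytes, -0.16 for epicardium (camera adjusted p = 0.0607), -0.19 for Schwann and neural crest cells and 0.42 for erythroid cells. The mean was negative for fatty acid oxidation (-0.01) and positive for endothelium (0.03) where the median had the other sign, and the test direction for smooth muscle was down. With 1 library left out, epicardial markers passed without sORF7 replicate 1 (camera adjusted p = 0.0446) or control replicate 1 (0.047), ion channels without control replicate 2 (0.0174) and DNA replication genes without control replicate 3 (0.0242).

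Of the 1156 genes, 71 changed at least 2-fold, 56 upward and 15 downward, and 3429 genes (23.1%) had no overlap between the 2 groups, where chance gives 10%. Without sORF7 replicate 1, 679 genes passed, and 627 in a fit of only these 6 libraries. The share of higher genes was 52.9% by counts and 69.5% (740 higher, 324 lower) by limma on log2(FPKM + 1). Leaving out both control libraries that stood apart, chosen after seeing the data, gave 1102 genes. Named genes that lost their call in some fits with 1 library left out, each with its largest edgeR adjusted p among them and the log2 fold change there, were Ceacam1 (0.209 at -0.59 without sORF7 replicate 1), Lingo4 (0.180 at -0.67 without control replicate 1), Tsen34l1 (0.139 at -0.67 without control replicate 3), Rpl28 (0.137 at 0.19 without sORF7 replicate 2), Fcrl2 (0.0846 at -0.73 without sORF7 replicate 3), Postn (0.0819 at -0.12 without control replicate 1), Adm (0.0804 at 0.36 without sORF7 replicate 2), Pgam1 (0.0740 at 0.11 without sORF7 replicate 3), Ndc80 (0.0706 at -0.31 without control replicate 3), Vegfa (0.0632 at 0.13 without sORF7 replicate 2) and Ermap (0.0542 at -0.94 without sORF7 replicate 1). Lingo4, Tsen34l1 and Ceacam1 each lost their call in 5 of the 6 fits, and Ceacam1 also with RLE size factors (adjusted p = 0.0510, edgeR) and by DESeq2 (0.0772). In the fit of only the 6 libraries, the calls of Ceacam1 (edgeR adjusted p = 0.199), Pgam1 (0.162), Rpl28 (0.132), Postn (0.106), Vegfa (0.0610), Olfml2a (0.0579), Fcrl2 (0.0533) and Col3a1 (0.0533) ended.

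The third comparison asked which genes sORF8 changed. Sarcomere genes were higher with sORF8 than with its control virus: 14 of 29 rose and 0 fell (24 and 0 adjusted over the list alone). The largest of these changes was in Myh6, which rose from 2804 ± 35.3 to 4886 ± 298 normalised CPM (SD, n = 3 each). That level with sORF8 stayed below the mean in the controls of sORF6 (6835) and sORF7 (6580). Cholesterol synthesis genes rose in 16 of 22 members, and chaperones of the endoplasmic reticulum in 8 of 21. Heat shock genes fell in 8 of 15 members and NRF2 and antioxidant genes in 8 of 24. The interferon-stimulated genes had a median of 0.16 and were not called as a list (camera adjusted p = 0.0853). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 559 genes passed, 302 higher and 257 lower, while limma on log2(FPKM + 1) called 256 higher and 287 lower. Of the 559, 513 also differed between the controls of sORF8 and sORF6, 511 of them in the opposite direction. The sORF8 controls enter both comparisons, so these changes cannot be credited to sORF8 alone.

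Myh6 (gene 29556, chromosome 15, 33605653 to 33634249, plus strand, Rnor_6.0) had a log2 fold change of 0.80 ± 0.07 and an edgeR adjusted p of 2.18e-06. Myom1 (0.35 ± 0.04) and Actn2 (0.26 ± 0.03), which encode proteins of the M-band and the Z-disc, also rose. The sarcomere list had a median of 0.19 and a camera adjusted p of 4.34e-30, and 0.000754 with an estimated correlation. Of 16 hypertrophy and fetal cardiac genes, 6 rose and 0 fell (9 and 2 adjusted over the list alone), with a median of 0.11 and a camera adjusted p of 6.80e-08, and 0.0230 with an estimated correlation. They included Nppa (0.37 ± 0.05), Myh7 (0.34 ± 0.06), Nppb (0.33 ± 0.06) and Ankrd1 (0.25 ± 0.04), while Acta1 (0.10 ± 0.05) did not pass, with an edgeR adjusted p of 0.329. Calcium handling genes rose in 5 of 32 members (8 rose and 2 fell adjusted over the list alone), namely Srl (0.37 ± 0.03), Casq2 (0.26 ± 0.03), Cacna1g (0.44 ± 0.06), Atp2a2, the calcium pump of the sarcoplasmic reticulum (0.25 ± 0.04), and Hrc (0.51 ± 0.08, named after its value was seen). The list median was 0.05, with a camera adjusted p of 0.000182 (adjusted p = 0.0594 with an estimated correlation).

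**Figure D3:**
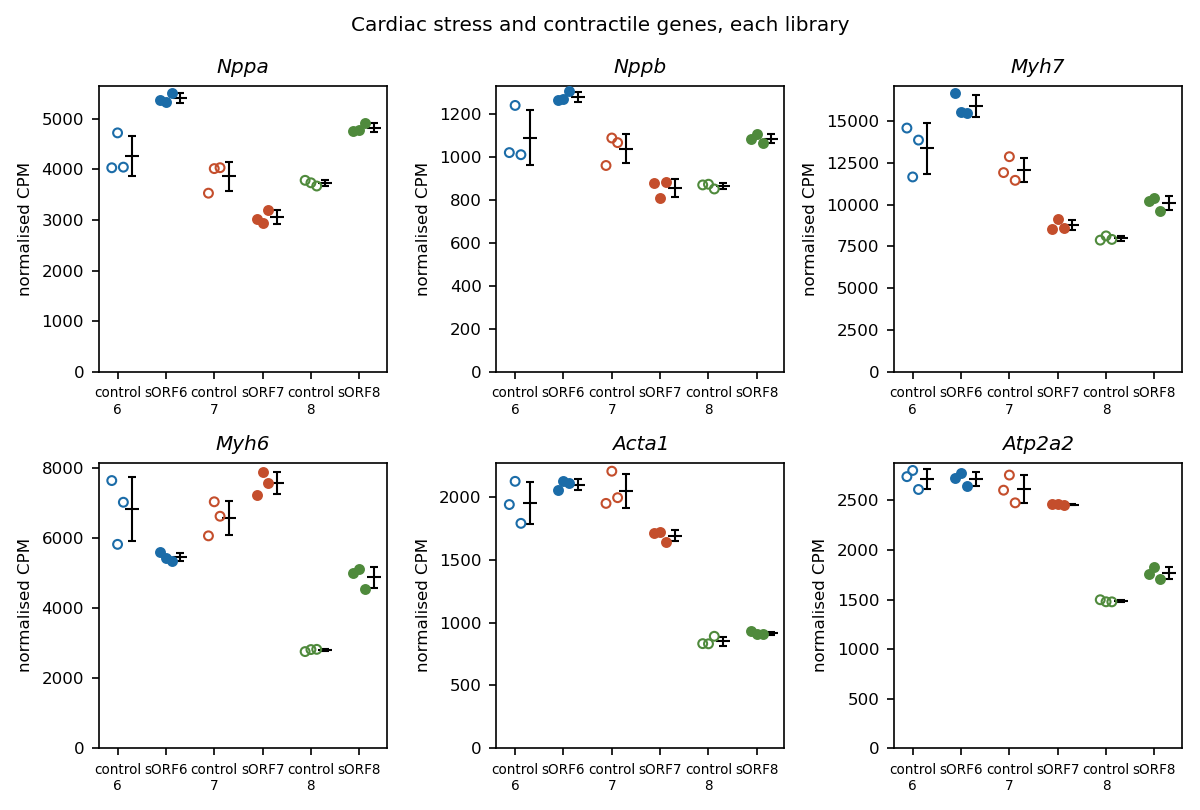
Normalised CPM (axes from 0) of Nppa, Nppb, Myh7, Myh6, Acta1 and Atp2a2 in each library, by group, with 3 points per group, filled for an sORF virus and open for its control virus, and the mean ± SD beside them. Nppa averaged 5405 with sORF6 against 4265 in its control, 3054 with sORF7 against 3859, and 4820 with sORF8 against 3729.

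Cholesterol synthesis genes had a median of 0.26 with sORF8 (20 of 22 rose adjusted over the list alone), with a camera adjusted p of 1.02e-39, and 3.28e-05 with an estimated correlation. Fdps, farnesyl diphosphate synthase, had a log2 fold change of 0.43 ± 0.05, Sc5d one of 0.34 ± 0.04 and Fdft1, squalene synthase, one of 0.28 ± 0.03. The endoplasmic reticulum chaperone list had a median of 0.15 (14 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 1.09e-13, and 0.00346 with an estimated correlation. Its leading members were Hyou1 (0.26 ± 0.03), Hspa5, the chaperone BiP (0.24 ± 0.03), and Sdf2l1 (0.45 ± 0.07). The heat shock list had a median of -0.21 (10 of 15 fell adjusted over the list alone), with a camera adjusted p of 3.61e-18, and 0.000363 with an estimated correlation. Hspa8, the constitutive HSP70 chaperone, fell from 2913 ± 106 to 2239 ± 48.3 normalised CPM, and Hsp90ab1 (-0.22 ± 0.03) and Dnaja1 (-0.30 ± 0.04) fell as well.

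In the NRF2 and antioxidant list, Gstp1, a glutathione transferase (gene 24426, chromosome 1, 219262166 to 219294966, plus strand), fell from 263 ± 4.85 to 172 ± 4.07 normalised CPM, the smallest adjusted p of the experiment (edgeR, 4.49e-08). Srxn1 (-0.55 ± 0.06) and Txnrd1, thioredoxin reductase (-0.25 ± 0.03), fell too. The list median was -0.14 (17 fell and 1 rose adjusted over the list alone), with a camera adjusted p of 4.89e-19, and 0.000304 with an estimated correlation. DNA replication genes rose in 4 of 27 members (12 adjusted over the list alone), namely Rrm2 (0.32 ± 0.06), Mcm5 (0.28 ± 0.06), E2f1 (0.42 ± 0.09) and Uhrf1 (0.24 ± 0.06, named after its value was seen), with a median of 0.15 and a camera adjusted p of 4.69e-10, and 0.0299 with an estimated correlation. NF-kB and cytokine genes rose in 5 of 27 (11 adjusted over the list alone), among them Il1b (0.89 ± 0.19), Nos2 (0.99 ± 0.24) and Cxcl1 (0.48 ± 0.11), with a median of 0.24 and a camera adjusted p of 8.31e-08, and 0.0174 with an estimated correlation. The p53 targets fell in 3 of 20 (4 adjusted over the list alone), namely Perp (-0.29 ± 0.04), Aen (-0.31 ± 0.05) and Cdkn1a (-0.16 ± 0.03), with a median of -0.05 and a camera adjusted p of 0.00295, and 0.0174 with an estimated correlation. MAPK feedback genes fell in 2 of 25 (4 adjusted over the list alone), Phlda1 (-0.20 ± 0.04) and Rasa1 (-0.18 ± 0.04), while Etv1 (-0.16 ± 0.04) had an edgeR adjusted p of 0.0556. That list had a median of -0.06 and a camera adjusted p of 0.00299, and 0.0174 with an estimated correlation.

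Several metabolic and growth lists were called with sORF8 at the preset correlation only. Nuclear-encoded oxidative phosphorylation genes had a median of 0.11 and rose in 7 of 78 members (17 adjusted over the list alone), among them Uqcr11 (0.32 ± 0.07), Uqcrh (0.26 ± 0.06) and Ndufa6 (0.27 ± 0.07), with a camera adjusted p of 6.10e-14 (adjusted p = 0.252 with an estimated correlation). Fatty acid oxidation had a median of 0.09, and its 2 of 30 members that rose, by either count, were Fabp3 (0.31 ± 0.06) and Acsl1 (0.15 ± 0.04), while Hadhb was at -0.10 ± 0.03 (camera adjusted p = 0.000656 for the list, adjusted p = 0.176 with an estimated correlation). Cardiac ion channels and junctions had a median of 0.15, where Kcnh2 rose (0.23 ± 0.04) and Gja1 (-0.11 ± 0.04) did not pass (2 of 22 rose adjusted over the list alone). That list had a camera adjusted p of 0.0156 (adjusted p = 0.140 with an estimated correlation, and 0.122 at the preset one without control replicate 1). Mitotic genes had a median of 0.16, with Hmmr (0.43 ± 0.10) and Anln (0.28 ± 0.07) higher, Top2a (0.32 ± 0.09) short of the threshold, and 9 of 30 higher adjusted over the list alone (camera adjusted p = 3.16e-06, adjusted p = 0.140 with an estimated correlation). Immediate early genes fell in 4 of 25 by either count, namely Klf6 (-0.26 ± 0.04), Fosl1 (-0.57 ± 0.10), Myc (-0.25 ± 0.06) and Klf4 (-0.15 ± 0.04, named after its value was seen), with a median of -0.09 and a camera adjusted p of 0.000251 (adjusted p = 0.0627 with an estimated correlation). Cytosolic ribosomal proteins fell in 7 of 74 (9 adjusted over the list alone), among them Rps2 (-0.20 ± 0.04), Rps3 (-0.18 ± 0.04) and Rpl4 (-0.12 ± 0.03), with a median of -0.11 and a camera adjusted p of 4.51e-14 (adjusted p = 0.252 with an estimated correlation).

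Among called, named loci with a mean log2 CPM of at least 1 and no overlap between groups, falls with sORF8 were led by those of Bpifb4 (gene 499925, chromosome 3, 149424392 to 149449350, plus strand), from 10.9 ± 0.764 to 2.83 ± 0.440 normalised CPM (log2 fold change -1.94 ± 0.17), and of Nell2 (-1.36 ± 0.12). Bpifb1 (-1.09 ± 0.18), Mmp16, a membrane-bound matrix metalloproteinase (-0.70 ± 0.09), Anxa3 (-0.70 ± 0.09), Gstp1 (-0.62 ± 0.04) and Plpp2 (-0.61 ± 0.16) fell as well. Within the same limits, the 8 largest rises were those of Nos2, Srgn (0.92 ± 0.22), Atp2b2 (0.91 ± 0.22), Il1b, the chemokine genes Ccl3 (0.86 ± 0.16) and Cxcl3 (0.83 ± 0.15), Abcb9 (0.85 ± 0.13) and Plek (0.83 ± 0.18). Only 11 of the 559 genes changed at least 2-fold, 3 upward and 8 downward. The 3 were Vat1l, Epyc and LOC100359687, all named after their values were seen.

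The other lists were not called with sORF8. Medians were -0.04 for glycolysis, 0.02 for hypoxia targets, 0.02 for TGF-beta and YAP targets (camera adjusted p = 0.0528), -0.05 for the integrated stress response (camera adjusted p = 0.0800) and 0.00 for autophagy and lysosome. For other cell types they were 0.03 for cardiac fibroblasts, 0.00 for smooth muscle and pericytes, 0.01 for endothelium, 0.05 for macrophages and leukocytes, 0.08 for epicardium, 0.12 for Schwann and neural crest cells and -0.03 for erythroid cells. Means were positive for glycolysis (0.01) and erythroid markers (0.57), as were their test directions, and the test direction for epicardial markers was down. With 1 library left out, TGF-beta and YAP targets passed without sORF8 replicate 2 (camera adjusted p = 0.0179), the integrated stress response without sORF8 replicate 1 (0.0288) or control replicate 2 (0.0330) and leukocyte markers without sORF8 replicate 3 (0.0485). TGF-beta and YAP targets also passed in the fit of only the 6 libraries (0.0170).

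Between the sORF8 libraries and their controls, 3643 genes (24.5%) had no overlap, where chance gives 10%. The count of 559 moved to 265 without sORF8 replicate 2, 341 without sORF8 replicate 1, and 366, 332 and 305 without control replicates 1, 2 and 3 in turn, and it rose to 934 with a correction for transcript length chosen after seeing the data. The interferon list passed without sORF8 replicate 3 (camera adjusted p = 4.89e-09) or control replicate 2 (0.00367). Named genes that lost their call in some fits with 1 library left out, each with its largest edgeR adjusted p among them and the log2 fold change there, were Myc (0.176 at -0.19 without sORF8 replicate 1), Rpl4 (0.156 at -0.11 without sORF8 replicate 2), Acsl1 (0.151 at 0.13 without control replicate 3), Rps3 (0.141 at -0.15 without sORF8 replicate 2), Atp2b2 (0.134 at 0.71 without control replicate 2), Plpp2 (0.130 at -0.55 without sORF8 replicate 3), Nos2 (0.12 at 0.80 without control replicate 2), Ndufa6 (0.12 at 0.24 without control replicate 3), Srgn (0.119 at 0.77 without sORF8 replicate 1), Uqcrh (0.111 at 0.20 without control replicate 3), Anln (0.110 at 0.24 without sORF8 replicate 2), Cxcl1 (0.0905 at 0.44 without control replicate 3), Cdkn1a (0.0819 at -0.13 without sORF8 replicate 2), Hmmr (0.0802 at 0.40 without control replicate 3), Rps2 (0.0634 at -0.18 without sORF8 replicate 2), Plek (0.0633 at 0.75 without sORF8 replicate 2), Uqcr11 (0.0608 at 0.28 without control replicate 1), Rasa1 (0.0574 at -0.16 without sORF8 replicate 1), E2f1 (0.0557 at 0.35 without sORF8 replicate 3) and Mcm5 (0.0538 at 0.23 without control replicate 2). Plpp2 and Rpl4 lost their call whichever of the 6 libraries was left out, and Atp2b2, Ndufa6, Acsl1 and Rps3 in 5 of the 6 fits. In a fit of only the 6 libraries, 815 genes passed, and the calls of Atp2b2 (edgeR adjusted p = 0.0618) and Srgn (0.0544) ended, while Gja1 (0.0271) and Top2a (0.0343) passed. By DESeq2, Top2a (adjusted p = 0.0082) and Etv1 (0.0398) passed.

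The responses to sORF6 and sORF7 differed for interferon-stimulated genes, with a median difference of -3.10, 40 of 44 members lower in sORF6 and 0 higher (41 and 0 adjusted over the list alone; camera adjusted p = 6.15e-172, and 0.000225 with an estimated correlation). Oasl, with log2 fold changes of -2.73 ± 0.20 and 1.74 ± 0.13, Cxcl10 (-1.89 ± 0.17 and 1.75 ± 0.13) and Tapbp, the tapasin gene of MHC class I peptide loading (-1.09 ± 0.08 and 0.81 ± 0.07), fell with sORF6 and rose with sORF7. The difference itself was tested by edgeR and passed for 1661 genes, with 726 higher and 935 lower in sORF6 relative to sORF7. For Tapbp the difference was -1.90 ± 0.10, with an edgeR adjusted p of 2.15e-09. Of 30 lists, 16 differed by camera at the preset correlation and 7 of these also with an estimated correlation, including the hypertrophy list with a median difference of 0.37 (10 members higher, 1 lower; 12 and 1 adjusted over the list alone) and the cholesterol list with 0.27 (12 higher, 0 lower; 18 and 0 adjusted over the list alone).

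Against sORF8, the sORF6 response differed for interferon-stimulated genes, with a median difference of -2.12 and 38 of 44 members lower (39 adjusted over the list alone; camera adjusted p = 5.94e-135, and 0.000744 with an estimated correlation). NF-kB and cytokine genes had a median difference of -0.76, with 22 of 27 lower (24 adjusted over the list alone; camera adjusted p = 2.00e-71, and 2.13e-06 with an estimated correlation). The 3 genes named by smallest p encode chemokines. Cxcl3 had log2 fold changes of -2.73 ± 0.20 with sORF6 and 0.83 ± 0.15 with sORF8, Cxcl1 of -1.95 ± 0.13 and 0.48 ± 0.11, and Ccl2 of -1.75 ± 0.11 and 0.27 ± 0.10. The differences, -3.57 ± 0.26, -2.43 ± 0.17 and -2.02 ± 0.15, had edgeR adjusted p of 1.75e-07, 1.35e-07 and 2.14e-07. In all, 548 genes differed, 129 higher and 419 lower in sORF6. The controls of these 2 experiments themselves differed in 5707 genes. Of 30 lists, 12 differed at the preset correlation and 6 of these also with an estimated correlation. DNA replication genes were among the 6, with a median difference of -0.34, 9 of 27 members lower and 0 higher (20 and 0 adjusted over the list alone).

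Between sORF7 and sORF8, NRF2 and antioxidant genes had a median difference of 0.29, with 13 of 24 members higher in sORF7 and 0 lower (18 and 0 adjusted over the list alone; camera adjusted p = 6.29e-28, and 4.40e-05 with an estimated correlation). Gstp1 rose with sORF7 (0.30 ± 0.04) and fell with sORF8 (-0.62 ± 0.04), as did Kdm1a, a histone demethylase gene (0.24 ± 0.04 and -0.51 ± 0.04), and Scd2, a stearoyl-CoA desaturase gene, fell with sORF7 (-0.36 ± 0.03) and rose with sORF8 (0.38 ± 0.03). The differences of 0.92 ± 0.05, 0.75 ± 0.06 and -0.74 ± 0.05 had edgeR adjusted p of 2.50e-08, 2.04e-07 and 3.46e-08. In all, 1148 genes differed, 565 higher and 583 lower in sORF7. The controls of these 2 experiments themselves differed in 5602 genes. Of 30 lists, 19 differed at the preset correlation and 8 of these also with an estimated correlation. Cholesterol synthesis had a median difference of -0.50, with 20 of 22 members lower by either count, and the sarcomere list one of -0.33, with 21 of 29 lower (25 adjusted over the list alone).

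Calls were compared across experiments, each with its own control libraries. Between sORF6 and sORF7, 243 genes fell with sORF6 and rose with sORF7, where independent lists would share 17.7, and 78 did the reverse, where chance gives 5.30. No gene rose in both (0, against 5.97 by chance), and 1 fell in both, against 15.7. The 1 was Vcam1, a leukocyte adhesion molecule gene named after its value was seen, with log2 fold changes of -0.42 ± 0.06 and -0.21 ± 0.06. Between sORF6 and sORF8, 17 genes rose in both (2.94 by chance), 13 fell in both (7.41), and 29 fell with sORF6 and rose with sORF8 (8.71). Between sORF7 and sORF8, 76 genes fell with sORF7 and rose with sORF8 (11 by chance), 54 did the reverse (10.6), 20 rose in both (12.4) and 9 fell in both (9.40). Across genes, which are not independent replicates, Spearman's rho of the fold changes was -0.30 for sORF6 with sORF7, 0.05 for sORF6 with sORF8 and -0.11 for sORF7 with sORF8, and Pearson's r was -0.08, -0.02 and 0.03. By edgeR, 0 genes were called in the same direction in all 3 experiments, of 1022 called higher and 1207 called lower in any. No chance value was computed for this count, so it cannot show that a common response was absent.

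Without an sORF, the control libraries of sORF8 differed from the other controls. Relative to the control of sORF6, sarcomere genes were lower (24 of 29 fell and 1 rose, 24 and 2 adjusted over the list alone, median log2 difference -0.53), as were fatty acid oxidation genes (26 of 30, 27 adjusted over the list alone, -0.53), mitotic genes (28 of 30, and 28 fell and 1 rose adjusted over the list alone, -0.63) and cholesterol synthesis genes (20 of 22 by either count, -0.50). Higher were heat shock genes (13 of 15 rose and 1 fell by either count, 0.58) and NRF2 and antioxidant genes (21 of 24 rose and 1 fell by either count, 0.52). Each of these 6 lists was called by camera with both correlations, the weakest being the mitotic list (adjusted p = 0.0232 with an estimated correlation). Interferon-stimulated genes had a median of -1.26, with 41 of 44 lower by either count and a camera adjusted p of 3.32e-20 (adjusted p = 0.0811 with an estimated correlation). Srxn1 and Gstp1 had log2 differences of 2.45 and 1.59, named after their values were seen.

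The joint edgeR test of the 3 control groups called 5714 genes, and 5707 differed between the controls of sORF8 and sORF6 (2808 higher, 2899 lower). Between the controls of sORF7 and sORF6, 1 gene passed the edgeR test and 1248 had an unadjusted p under 0.05. The 1 was Cdkn1a, 0.23 higher on the log2 scale in the control of sORF7, named after its value was seen. The interferon list had a median difference of 0.42 between these 2 controls (0 of 44 over all genes, 28 higher adjusted over the list alone, camera adjusted p = 1.92e-34, and adjusted p = 0.0530 with an estimated correlation). The labels give no preparation or sequencing date, and each control virus was measured in 1 experiment only. The sORF8 virus libraries lay apart on the first principal component together with their controls. A difference of the control virus therefore cannot be told apart from a difference of the whole experiment.

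The authors' deposited table gave a q-value under 0.05 for 3928 genes with sORF6, 4906 with sORF7 and 4030 with sORF8. Of these, 3790, 4693 and 3917 were among the genes tested here. All 574, 1156 and 559 genes called here were among them, in the same direction. The deposited values come from the same counts and far more genes passed there, so this overlap is not independent support.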

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

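The tests of leukocyte share and of infection strength were chosen only after the interferon result was seen. Interferon-stimulated genes ran in opposite directions with sORF6 (list median -1.87) and sORF7 (0.91), each against its own control virus. The list also differed between control groups, where no sORF was present. Its median was 0.42 higher in the control of sORF7 than in that of sORF6, and it was lower in the control of sORF8. Both differences were called by camera at the preset correlation only. Fewer leukocytes in the sORF6 cultures would lower leukocyte markers along with the interferon list, but the macrophage and leukocyte markers had a median log2 fold change of -0.28 (SE 0.193 over genes), which argues against that as the whole cause. A different strength of infection between each virus and its control may be a candidate explanation and stays open: over 14801 genes outside the interferon and NF-kB lists, the sORF6 and sORF7 fold changes had a Spearman rho of -0.29, which an action of the sORFs could give as well. Over 12511 genes, the fold changes also followed effective transcript length in opposite directions (Spearman rho 0.228 for sORF6 and -0.129 for sORF7). Whether that trend contributed to the rho of -0.29 was not tested. Viral transcripts were not analysed here, so infection strength and an action of the sORFs cannot be told apart. An effect of each sORF on interferon signalling remains a hypothesis.

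Responses that differed between experiments, by a test of the difference itself, are listed here because the experiments shared a design. The controls were not alike, as 5707 genes differed between those of sORF8 and sORF6 and 5602 between those of sORF8 and sORF7. A different response to sORF8 therefore cannot be told apart from this difference of its controls. Between sORF6 and sORF7, 1661 genes differed. The difference of log2 fold changes (sORF6 minus sORF7) was -4.46 for Oasl, -1.90 for Tapbp and -3.65 for Cxcl10. List medians of the difference were 0.37 for hypertrophy and fetal cardiac genes, 0.26 for sarcomere genes, -3.10 for interferon-stimulated genes, -0.97 for NF-kB and cytokine genes, -0.21 for p53 targets, -0.27 for NRF2 and antioxidant genes and 0.27 for cholesterol synthesis.

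Between sORF6 and sORF8, 548 genes differed. The difference (sORF6 minus sORF8) was -2.43 for Cxcl1, -3.57 for Cxcl3 and -2.02 for Ccl2. List medians were -2.12 for interferon-stimulated genes, -0.76 for NF-kB and cytokine genes, 0.14 for heat shock genes, -0.34 for DNA replication genes, 0.077 for NRF2 and antioxidant genes and -0.22 for cholesterol synthesis.

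Between sORF7 and sORF8, 1148 genes differed. The difference (sORF7 minus sORF8) was 0.92 for Gstp1, -0.74 for Scd2 and 0.75 for Kdm1a. List medians were -0.40 for hypertrophy and fetal cardiac genes, -0.33 for sarcomere genes, -0.12 for calcium handling, -0.14 for TGF-beta and YAP targets, 0.23 for heat shock genes, 0.15 for p53 targets, 0.29 for NRF2 and antioxidant genes and -0.50 for cholesterol synthesis.

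Other splits of the same libraries were counted for each of these results. For the differences, 1 of 100 splits, the real one, gave as many genes in each case. The highest of the others gave 381 (sORF6 against sORF7), 249 (sORF6 against sORF8) and 254 (sORF7 against sORF8). The other splits exchanged virus and control labels within 1 or both experiments. These counts therefore speak to an effect in at least 1 of the 2 experiments and cannot show by themselves that the responses differ. For the single experiments, 1 of 10 splits gave as many genes as the real split (574, 1156 and 559), with highest others of 2, 0 and 1, and 10 splits are too few for a share under 0.05.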

How the results depend on the processing

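The calls of sORF6, sORF7 and sORF8 kept their direction in every setting tried. Length-corrected offsets, thinning and leaving out 2 control libraries were chosen after seeing the data. With RLE size factors 573, 1147 and 548 genes passed, without a low-count filter 522, 1041 and 486, with DESeq2 574, 1106 and 664, with limma on FPKM 526, 1064 and 543, and thinned to equal depth 548, 1105 and 534. A fit of only the 6 libraries of an experiment gave 318, 627 and 815, and the cause was not tested. The order of the experiments changed with it: sORF8 had the most genes in these fits, where sORF7 had the most in the main fit. The counts therefore do not rank the sORFs. A 2-fold threshold left 136, 71 and 11. Length-corrected offsets gave 684, 1437 and 934; for 934 the cause was not tested. Of 8, 16 and 17 lists called at the preset correlation, 3, 9 and 10 were called with an estimated correlation.

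Leaving out 1 library gave 368 to 529 genes for sORF6, 679 to 955 for sORF7 and 265 to 385 for sORF8, and the cause was not tested. It gave 1273 to 1675, 409 to 582 and 794 to 1108 for the differences of sORF6 from sORF7, sORF6 from sORF8 and sORF7 from sORF8, and 4825 to 6199 for the control groups. Lists called ranged from 8 to 13 for sORF6 (13 without control replicate 1), 16 to 17 for sORF7 and 16 to 19 for sORF8. Of the values of named genes with 1 library left out, 140 lost their call, 6 gained one and 0 reversed. Cytosolic ribosomal proteins, not called with sORF6, were called as lower without control replicate 1 (camera adjusted p = 0.00679) or replicate 3 (0.0266) and as higher without control replicate 2 (0.00553, of a range from 0.00553 to 0.581 with 1 library left out, and 0.846 with an estimated correlation); the cause was not tested.

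Any pairing of the libraries by replicate number was weak: same-number deviations correlated at -0.02 to 0.18 over 9 pairs, 2 of them over 0.1. Of the 9, 6 correlated best with their own number, a count that was not tested against chance, so a weak pairing cannot be excluded. With the replicate block 523, 1021 and 458 genes passed, and 1526, 495 and 1062 for the differences. Of the values of named genes, 13 lost their call with the block, 3 gained one and 0 reversed. In simulated counts at these depths 74% to 82% of 2-fold changes were recovered. Recovery was not split by expression level or depth.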

Other observations

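The pathway tests, the exchange of control labels and the test of cardiomyocyte share were chosen only after the results were seen. Antigen processing and presentation genes, most of them outside the fixed lists, fell with sORF6 in 22 of 68 members (median -0.15, camera adjusted p = 7.18e-18 over 250 pathways of the table's own annotation, and 0.00240 with an estimated correlation). With sORF7, 26 of the 68 rose and 0 fell (median 0.20, camera adjusted p = 2.33e-18, and 0.0123 with an estimated correlation). Complement and coagulation genes fell with sORF6 in 11 of 51 members and rose in 1 (camera adjusted p = 5.83e-06, and 0.0204 with an estimated correlation).

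With sORF8, propanoate metabolism genes rose in 7 of 32 members (median 0.20, camera adjusted p = 4.74e-09, and 0.0265 with an estimated correlation), and genes for ketone bodies in 4 of 10 (camera adjusted p = 0.000178, and 0.0265 with an estimated correlation). Fatty acid degradation genes rose in 3 of 41 (camera adjusted p = 0.0242; adjusted p = 0.405 with an estimated correlation). With sORF7, genes for unsaturated fatty acids fell in 5 of 25 members (camera adjusted p = 6.91e-05, and 0.0339 with an estimated correlation).

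Control replicate 2 of the sORF6 experiment and control replicate 1 of the sORF7 experiment stood apart within their groups. A swap of the pair was tested by exchanging their labels: the median interferon difference between the 2 control groups went from 0.42 to -0.07, a ratio of -0.168. That would speak against a swap only if the 2 controls truly differed in these genes, which the design does not require. The count of genes points the other way, as the exchanged labels called 1271 genes where the given labels called 1. The exchange therefore cannot decide on a swap. Transcript length bias is a candidate explanation: the deviation of control replicate 2 of sORF6 followed effective length with a Spearman rho of -0.502 across genes, and that of control replicate 1 of sORF7 with 0.408. Control replicate 3 of sORF6 (0.410) and of sORF7 (-0.351) had trends of similar size, each opposite in sign to the trend of the library that stood apart in its group. Each deviation was taken from the other 2 libraries of its group, so these values are not independent of the pair. They cannot tell whether the trend was particular to the pair. No biological explanation was tested.

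Changes with sORF8 ran opposite to the difference of its control from the control of sORF6: Pearson's r across genes was -0.604. Independent noise in the shared control libraries alone gave a lowest r of -0.262 in 100 simulations (covariance -0.0361 against a simulated median of -0.00933). That argues against such noise as the whole cause. The simulation held no deviation common to the 3 sORF8 controls, which would enter both differences with opposite sign, so it cannot decide on that. Thinning to equal depth left r at -0.602, which argues against sequencing depth as the whole cause. A higher cardiomyocyte share would lower the markers of all other cell types alike, but 55 such markers had a median of 0.03 (SE 0.0344 over genes). Heat shock genes had a median of -0.21 (SE 0.0729 over genes), but they are not markers of a cell type, so their fall does not bear on cell share. It stays open, as a hypothesis that may be followed up, whether the sORF8 virus moved the cells toward the state of the other controls. Whether its control virus differed in preparation stays open as well, since each control was measured in 1 experiment. All libraries of the sORF8 experiment lay apart from the others on the first principal component. A difference of the whole experiment cannot be told apart from one of its control virus. For the 3 control groups, 2 of 100 splits, the real one included, gave as many genes as the real 5714. The other, with 5947, kept the 3 sORF8 controls together. The count therefore speaks to the sORF8 controls against the rest and not to the split of the other 2 control groups.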
